A study of Homo sapiens with 16 samples.

How the data were processed

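Reconstituted human epidermis, a cultured tissue of keratinocytes, had been kept for 24 h without cytokine or with IL-1a (10 ng/ml), IL-1F5, IL-1F6, IL-1F8 or IL-1F9 (5 µg/ml each). Biotin-labelled complementary DNA from each of 16 cultures had been put on a whole-transcript Affymetrix array. The groups are those of the labels: untreated 2, IL-1a 3, IL-1F5 3, IL-1F6 3, IL-1F8 3 and IL-1F9 2 arrays. The deposited values are RMA expression values on the log2 scale, 1 per probe set. The submitters' processing notes name affy, RMA and limma, whose versions are not given in the sources used here. RMA corrects background, normalizes by quantiles and summarizes the probes of a set. The columns of the table used were close in distribution but not identical, with medians of 5.84 to 5.99 and standard deviations of 1.91 to 2.20. No counts lie behind array values, so the number of arrays limits the precision.

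The table used held 26681 probe sets, of which 95 on sex-linked genes were left out. Before these were left out, 17851 carried exactly 1 gene symbol, 1585 carried several and 7245 had no entry in the annotation table. By Entrez ID 17821 of the 1-symbol probe sets matched the gene table and 30 did not. For the 690 genes with over 1 probe set, the probe set with the highest mean over the 16 arrays was kept, giving 16877 genes. On chromosome 1, 321 of 2061 protein-coding genes (15.6%) were among them, against 75.9% to 90.1% on the other chromosomes, so most of its genes were not analysed here. Close paralogs such as SAA1 and SAA2 or SERPINB3 and SERPINB4 share sequence, and a probe set may read more than its named gene. The 8759 probe sets with several or no symbols that remained were tested and adjusted together with all other probe sets, without naming genes. Of these 8759, 0 passed in any comparison by limma, with the same threshold.

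Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) with 6 group means over all 16 arrays, which left 10 residual degrees of freedom and a prior of 7.1. The comparisons were each cytokine against untreated, the mean of IL-1F6, IL-1F8 and IL-1F9 against IL-1a and against IL-1F5, and the 3 pairs of those agonists. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes within each of the 10 comparisons, with a threshold of 0.05 and no fold minimum. Differences are given on the log2 scale with limma's standard error (SE) and, where an interval is given, its 95% confidence interval.

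Gene lists were fixed before the data were examined, 29 in all, covering inflammatory, antimicrobial, barrier, protease, growth, metabolic and stress genes of epidermis and markers of other cell types. The late cornified envelope and small proline-rich protein lists had 0 and 2 measured members, under the minimum of 4, which left 27. Lists were tested with limma camera at a preset correlation of 0.01, adjusted over the lists within each comparison, and members were also counted by the gene test adjusted over the list alone. As alternatives, camera estimated the correlation within each list, and fry, a rotation test, asked whether a list's genes moved on balance one way (directional) or changed in either direction (mixed), neither of which compares a list with other genes. Named genes are the 20 with the largest positive and the 10 with the largest negative difference for each cytokine against untreated (10 each way between cytokines) that passed the threshold with arrays that did not overlap, plus any member of the fixed lists. Beyond these, the position of a called gene in another comparison is given as a value.

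The tests were tried on simulated data. With 200 genes changed by a log2 of 1 or 2 in 10 draws of 16877 genes, limma recovered 84.7% and 99.8% of them for IL-1a against untreated, 85.5% and 99.9% for IL-1F6, and 75.9% and 99.9% for IL-1F9. False calls were 5.34%, 5.5% and 4.61% of the calls. These draws took each gene independently of the others, so the shares need not hold for the correlated genes of real arrays. With IL-1F8, 78 genes differed from untreated by a log2 of 1 or more in size, and 0 passed. A count of 0 therefore does not show that changes of that size are absent. Unchanged arrays were drawn 100 times from the residuals, keeping the correlation between genes, to count the lists and genes called by chance. For IL-1a, 4 of these 100 sets called any gene, and the most called in a set was 1254. Because every cytokine shares the 2 untreated arrays, correlations, overlaps and shared signs of genes between cytokines are given beside values simulated for unchanged groups. These values came from 1000 draws for correlations and 100 for the rest. No such value was simulated for lists that shift alike with several cytokines. Principal components were computed over the 16877 genes, and correlations between arrays over the probe sets.

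The alternatives chosen beforehand were a variance trend with robust moderation, leaving out dim genes, the mean of a gene's probe sets, every probe set tested, quantile normalization again, centring on the median, only the groups compared, array weights, a fold minimum of 1 on the log2 scale, the replicate number as a block, both other list tests, other controls for the correlations, and leaving out each of the 16 arrays. A further 3 were added after the data were seen: the arrays' standard deviation as a covariate, leaving out the 2 outlying IL-1F5 arrays, and leaving out the IL-1F5 group. Control probe sets were not used here, so the planned covariate for RNA quality was not run. Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6 read the files, and matplotlib 3.10.9 drew the plots.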

Results

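Transcript levels were measured on 16 whole-transcript arrays from reconstituted human epidermis, a layered keratinocyte culture, after 24 h with or without a recombinant cytokine of the IL-1 family. The groups were untreated (2 arrays), IL-1a at 10 ng/ml (3 arrays), and IL-1F5 (3), IL-1F6 (3), IL-1F8 (3) and IL-1F9 (2), each at 5 µg/ml. IL-1F6, IL-1F8 and IL-1F9 are now named IL-36 alpha, beta and gamma and act through the IL-36 receptor, whereas IL-1F5 is the antagonist of that receptor. Array medians lay between 5.84 and 5.99 on the log2 scale. The arrays' median correlation with the other 15 was 0.986 to 0.993, except in IL-1F5 replicates 1 and 2, where it was 0.968 and 0.98. IL-1F5 replicate 1 also had the narrowest spread, with a standard deviation of 1.91 against 2.08 to 2.20 in the others. The number of arrays limits the precision, and the p-values measure only the spread between these arrays, since nothing in the labels says that the cultures came from separate donors. Most genes of chromosome 1 were not analysed here, which takes in the S100, late cornified envelope, loricrin, filaggrin and involucrin genes and all but 2 of the 11 small proline-rich protein genes. Of the 18 members of the antimicrobial list 9 were measured, and the beta-defensin genes DEFB4A and DEFB103A were not among them.

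The comparison of IL-1a with untreated epidermis asked which transcripts this cytokine changed. The genes that rose by the largest amounts were SAA2 and CFB, of the acute phase and complement, followed by HEPHL1 and then by LCN2 and PI3, of antimicrobial defence. SAA2 (probe set 8180303), which encodes serum amyloid A2, rose from 5.06 ± 0.04 (SD, n = 2) to 9.54 ± 0.44 (SD, n = 3), or 22.4-fold (log2 difference 4.48, SE 0.694). CFB (probe set 8179351), complement factor B of the alternative pathway, rose 9.59-fold (3.26, SE 0.273), from 5.66 ± 0.06 (SD, n = 2) to 8.92 ± 0.35 (SD, n = 3). HEPHL1, a copper-dependent ferroxidase on none of the fixed lists, rose 5.86-fold (2.55, SE 0.469). LCN2, an iron-siderophore-binding antimicrobial lipocalin, rose 4.28-fold (2.10, SE 0.383), and PI3, the elastase inhibitor elafin, rose 3.07-fold (1.62, SE 0.237). CYB5R2, a cytochrome b5 reductase, rose 2.1-fold (SE 0.191 on the log2 scale). KRT77 (probe set 7963502), a type II keratin, fell by 1.93 on the log2 scale (SE 0.193), from 9.73 ± 0.18 (SD, n = 2) to 7.80 ± 0.25 (SD, n = 3). UPK1A, a uroplakin, ACSM6, the transmembrane protein gene TMEM164 and SLC8A1, a sodium-calcium exchanger, fell as well, with log2 differences of -1.96, -1.86, -1.60 and -1.59. PLLP, TMEM63C, CPE, HLA-DMA (a chaperone of class II antigen presentation) and KLK1 fell, with log2 differences of -1.35, -1.32, -1.22, -1.13 and -1.13, and the remaining 4 lower genes lay between -1.13 and -0.97.

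In all, 20 of 16877 genes passed an adjusted p of 0.05 in limma, 6 higher and 14 lower, with adjusted p-values of 1.67e-05 for CFB, 0.000126 for KRT77, 0.00688 for PI3, 0.0106 for SAA2 and 0.04 for LCN2. For each of the 20, every IL-1a array lay on the same side of both untreated arrays, a separation that chance gives 20% of genes. At an unadjusted p under 0.05 there were 721 genes, where chance gives 844. The count was lower with an array of either group left out: 8, 12 and 10 without IL-1a replicates 1, 2 and 3. It was also lower without either untreated array, which leaves 1 in that group. The count was 32 with the arrays' spread as a covariate and 44 with array weights. Fewer arrays in a group also give a larger SE, so lost calls do not show that the differences rest on single arrays. All 20 genes kept their direction in each of the 16 fits that left out an array. SAA2 ran from 4.26 to 4.70 in these fits, UPK1A from -2.03 to -1.88 and APOL3, which varied more, from -1.50 to -0.75. With an array left out, CFB and KRT77 passed in 16 of 16 fits and SAA2 in 12, whereas HEPHL1, LCN2, CYB5R2, UPK1A, TMEM63C and ULK4 passed in 5, 7, 7, 4, 5 and 3.

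Of the gene lists, the acute phase and complement list rose with IL-1a: 11 of its 14 measured members were above untreated, with a median log2 difference of 0.49 (adjusted p = 2.6e-13, and adjusted p = 0.0392 with an estimated correlation). Adjusted over the list alone, 7 members rose, among them SAA1 (1.46) and the classical complement proteases C1R (0.59) and C1S (1.17), while over all genes tested 2 did, SAA2 and CFB. NF-kB targets rose with a median of 0.32 over 17 genes (adjusted p = 1.66e-10, and adjusted p = 0.0652 with an estimated correlation). In this list 6 members rose adjusted over the list alone, among them SOD2 (1.25), TNFAIP3 (0.74) and NFKB2 (0.72), and 0 over all genes. Antimicrobial genes rose with a median of 0.22 over 9 genes (adjusted p = 5.12e-05, and adjusted p = 0.0652 with an estimated correlation), with 3 members adjusted over the list alone (LCN2, PI3 and RNASE7) and 2 over all genes. The difference of RNASE7, 0.71, rested on 1 untreated array: it was 0.11 without untreated replicate 1 and 1.31 without replicate 2. The list of activation-associated keratins and partners, in which KRT16 was the 1 keratin measured of 12 genes, rose with a median of 0.15 (adjusted p = 8.23e-06, and adjusted p = 0.155 with an estimated correlation). The 3 members that rose adjusted over the list alone were: SERPINB4, a protease inhibitor (0.88), GJB6, a gap junction protein (0.66), and TMPRSS11D, an airway-type serine protease (1.09), while KRT16 stood at 0.12. Cell cycle genes were above untreated in 27 of 28 members, with a median of 0.25 (adjusted p = 1.17e-05, and adjusted p = 0.41 with an estimated correlation). Cholesterol synthesis and the list of kallikreins and inhibitors rose with medians of 0.20 and 0.12 (adjusted p = 0.000932 and 0.0368, and adjusted p = 0.363 and 0.41 with an estimated correlation). Terminal differentiation fell with a median of -0.10 (adjusted p = 0.0197, and adjusted p = 0.404 with an estimated correlation), with 1 member, KRT77, passing adjusted over the list alone and over all genes.

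These 8 lists of 27 came from limma camera with a preset correlation of 0.01, a setting that was permissive on these arrays. In 100 simulated sets of unchanged arrays with the observed residuals it called a mean of 3.64 lists for IL-1a, at most 10, and 9 sets gave 8 or more. The estimated correlation called a mean of 0.03, and fry, a rotation test, called 1 list for IL-1a by direction and 7 in its mixed form. The call was lost for cell cycle without IL-1a replicate 1, for cholesterol synthesis without untreated replicate 2, for terminal differentiation without untreated replicate 1 or IL-1a replicate 1 or 2, and for kallikreins and inhibitors without any of these 3 or IL-1F5 replicate 3. Among the markers of other cell types, AQP5, a water channel of sweat glands, was 1.36 above untreated and KRT77, which the sweat gland list also holds, was the keratin that fell. Both passed adjusted over that list alone, and the list itself had a median of -0.13 (adjusted p = 0.142).

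**Figure D1:**
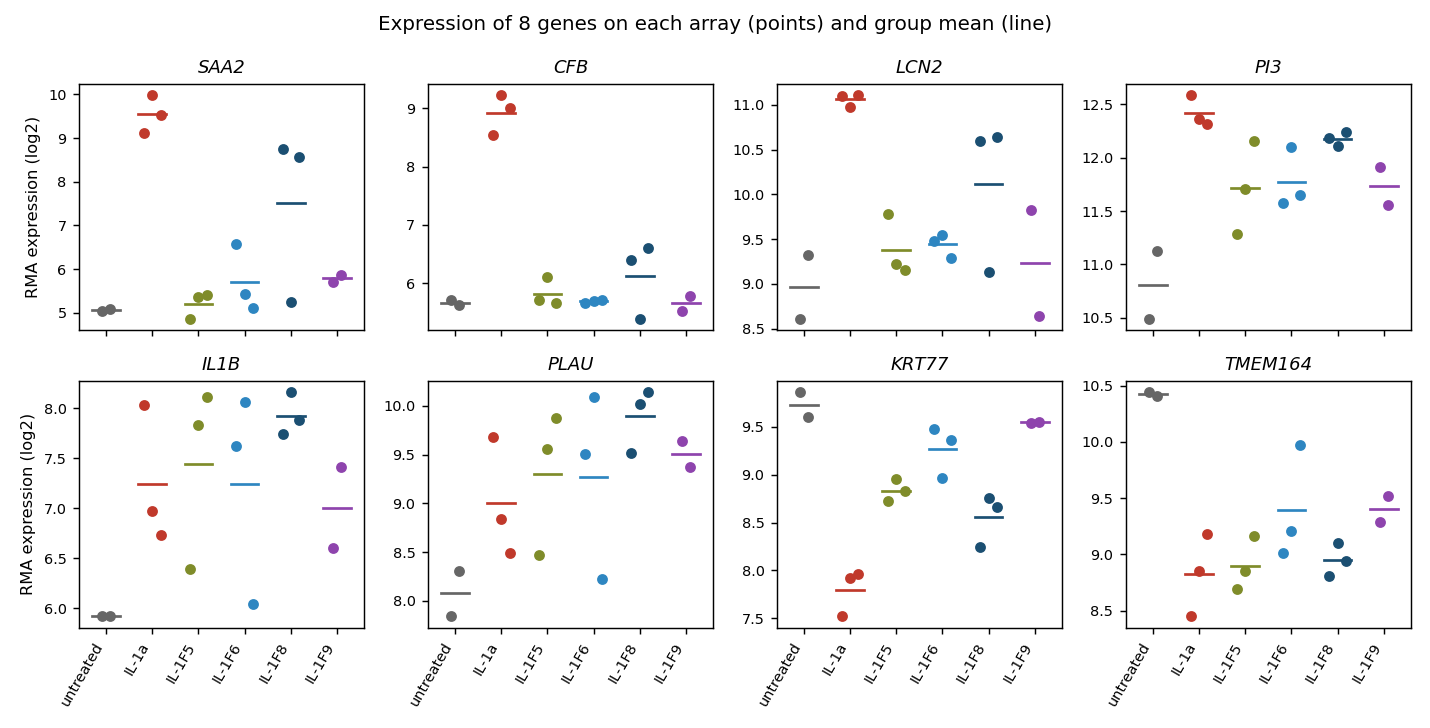
Expression of 8 genes on each array (y axis, RMA value on the log2 scale), grouped by treatment on the x axis; each point is an array and each line the mean of its group of 2 or 3 arrays. SAA2 and CFB are high on the 3 IL-1a arrays, and in IL-1F8 the SAA2 points split between 8.56 and above on replicates 1 and 3 and 5.24 on replicate 2.

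The comparison of IL-1F5, the receptor antagonist, with untreated epidermis asked which transcripts it changed; each of the 5 genes that passed the test was lower. TMEM164 fell by 1.52 on the log2 scale (SE 0.247), from 10.42 ± 0.02 (SD, n = 2) to 8.90 ± 0.24 (SD, n = 3). SLC8A1 fell by 1.39 (SE 0.199), APOL4, an apolipoprotein L gene, fell by 1.26 (SE 0.204), ULK4, a kinase-like gene, fell by 1.19 (SE 0.186) and RAB11FIP4, a Rab11 effector, fell by 0.99 (SE 0.165). SAA2 and CFB stood at 0.15 and 0.16 above untreated, with 95% confidence intervals of -1.31 to 1.61 and -0.42 to 0.73. The cytokine transcripts IL1A and IL1B stood at 1.31 and 1.52, with adjusted p-values of 0.119 and 0.177. Adjusted over their lists alone, IL1A and the antimicrobial genes PI3 (0.91) and SLPI (0.86) rose with IL-1F5 too (adjusted p = 0.0247, 0.0111 and 0.0116), and none of them passed over all genes. PI3 stood at 0.59 without untreated replicate 1.

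Barrier genes lay lower with IL-1F5. The epidermal lipid barrier list was below untreated in 20 of 22 members, with a median of -0.42 (adjusted p = 1.27e-05, and adjusted p = 0.764 with an estimated correlation). Adjusted over the list alone, 3 members fell, the lipoxygenase ALOXE3 (-0.63), the fatty acid hydroxylase CYP4F22 (-0.49) and PNPLA1, which acts in acylceramide synthesis (-0.75), and over all genes 0 did. Terminal differentiation was below untreated in 17 of 18 members, with a median of -0.16 (adjusted p = 0.00132, and adjusted p = 0.764 with an estimated correlation). KRT77 (-0.89), the transglutaminases TGM3 (-1.06) and TGM5 (-0.92) and CALML5 (-0.73) fell adjusted over the list alone, and 0 over all genes. Other cytokines and growth factors rose with a median of 0.31 and metallothioneins with NRF2 targets with a median of 0.44 (adjusted p = 0.00737 and 0.0373), each at adjusted p = 0.764 with an estimated correlation and with 0 members passing adjusted over the list alone. Of the leukocyte markers, LCP1 (-1.39) and ITGAM (-0.75) were lower adjusted over that list alone, and the list had a median of 0.20 (adjusted p = 0.795). IL-1F5 replicates 1 and 2, the arrays least correlated with the rest, belong to this group. Without both, 7 lists passed in place of 4, but that fit holds 1 IL-1F5 array and assumes that it varies like the arrays of the other groups.

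In limma 5 of 16877 genes passed for IL-1F5, all lower, with adjusted p-values of 0.0368 (SLC8A1), 0.042 (TMEM164, APOL4 and ULK4) and 0.048 (RAB11FIP4), and 3003 had an unadjusted p under 0.05 where chance gives 844. The 3 IL-1F5 arrays lay below both untreated arrays for each of the 5, a separation that chance gives 20% of genes in either direction. The gene count moved over 1.5 times with each of the 16 arrays left out: to 2097 without IL-1F5 replicate 3, 58 and 19 without IL-1F6 replicates 3 and 1, 9 without IL-1a replicate 3 or IL-1F8 replicate 2, 8 without IL-1a replicate 1 and 3 without IL-1F6 replicate 2. It was 1 without untreated replicate 2 or IL-1F9 replicate 1 or 2, and 0 without untreated replicate 1, IL-1a replicate 2, IL-1F5 replicate 1 or 2 or IL-1F8 replicate 1 or 3. Processing moved it both ways. It was 15 with dim genes left out, 110 with the arrays centred on their medians, 421 with the replicate number as a block and 1807 with array weights, which gave replicates 1, 2 and 3 of IL-1F5 weights of 0.21, 1.63 and 0.26. It was 1 with the mean of a gene's probe sets, and 0 with every probe set tested, with only the 2 groups in the fit, with the arrays' spread as a covariate and without both outlying arrays (1 IL-1F5 array left, with the spread taken from the other groups). The spread covariate gave 7 lists, and fry gave 1 by direction and 4 in its mixed form. The median of other cytokines was 0.19 after quantile normalization, and that of terminal differentiation was -0.25 with the arrays centred. Of the simulated unchanged sets, 55 of 100 gave 4 or more lists for IL-1F5, with a mean of 4.2. The metallothionein call ended without either untreated array or without IL-1F5 replicate 2 or 3.

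The comparison of IL-1F6 with untreated epidermis called no single gene. Antimicrobial genes rose as a list, with a median of 0.46 over 9 genes (adjusted p = 0.0288, and adjusted p = 0.787 with an estimated correlation). Adjusted over the list alone, 4 members rose: PI3 (0.97), the ribonuclease RNASE7 (0.73), the protease inhibitor SLPI (0.67) and the cathelicidin gene CAMP (0.46). RNASE7 stood at 0.14 without untreated replicate 1 and at 1.33 without replicate 2. The matrix metalloproteinase and plasminogen list, which also holds the protease inhibitors TIMP1, TIMP2 and TIMP3 and the receptor PLAUR, was above untreated in 14 of 16 members (median 0.29, adjusted p = 0.0288, and adjusted p = 0.787 with an estimated correlation), and other cytokines and growth factors in 14 of 15 (median 0.17, with the same pair of adjusted p-values). The lipid barrier list was below untreated in 19 of 22 members (median -0.19, adjusted p = 0.00152, and adjusted p = 0.787 with an estimated correlation). Terminal differentiation was below it in 16 of 18 (median -0.12, adjusted p = 0.0146, and adjusted p = 0.787 with an estimated correlation). Cell cycle genes fell with a median of -0.16 (adjusted p = 0.0297, and adjusted p = 0.823 with an estimated correlation). None of these last 5 lists had a member passing adjusted over the list alone. CFB stood at 0.04 (95% confidence interval -0.54 to 0.61) and SAA2 at 0.64 (-0.82 to 2.10). The IL-1F6 arrays ran from 5.11 to 6.57 in SAA2, against 5.03 and 5.09 on the untreated arrays. Of the markers of other cell types, ENG, an endothelial gene, was 0.56 higher adjusted over its list alone. Centring the arrays on their medians moved the median gene by -0.11 here. The sign of the 6 list medians stayed, but their sizes depended on the scaling: with centring, other cytokines stood at 0.06 (0.08 after quantile normalization), the matrix metalloproteinase list at 0.18, terminal differentiation at -0.23, the lipid barrier at -0.30 and the cell cycle at -0.27. The list tests were not repeated with either scaling.

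For IL-1F6 limma called 0 genes, with 1379 at an unadjusted p under 0.05 (chance 844) and a smallest adjusted p of 0.392, and fry called 0 lists in either of its forms. Without IL-1F6 replicate 3, 13 genes passed, and without untreated replicate 1 the 6 lists came to 1, terminal differentiation, and with the arrays' spread as a covariate to 3. The matrix metalloproteinase call also ended without IL-1F6 replicate 2 and the cell cycle call without replicate 3. In 24 of 100 simulated unchanged sets there were 6 or more lists for IL-1F6.

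The comparison of IL-1F8 with untreated epidermis showed the broadest set of list shifts, 15 of 27, though no single gene passed over all genes. The matrix metalloproteinase and plasminogen list rose with a median of 0.42 over 16 genes (adjusted p = 3.5e-07, and adjusted p = 0.114 with an estimated correlation). Adjusted over the list alone, 7 members rose and 1, MMP7 (-0.49), fell, against 0 over all genes. The largest were MMP10, a stromelysin (2.01, SE 0.575), PLAU, the urokinase activator of plasminogen (1.82, SE 0.46), MMP9, a gelatinase (1.74, SE 0.529), the collagenase MMP1 (1.44, SE 0.521) and the urokinase receptor PLAUR (1.18), and the other 2 were the protease inhibitors TIMP1 (0.62) and TIMP3 (0.49). Of the EGF family ligands, HBEGF (1.00), NRG1 (0.97) and EPGN (0.90) rose and BTC (-1.07) fell adjusted over the list alone, with 0 over all genes (list median 0.12, adjusted p = 0.0115, and adjusted p = 0.164 with an estimated correlation). EPGN stood at 0.48 without untreated replicate 2. IL1B (2.00, SE 0.524), IL1A (1.51, SE 0.366) and the receptor antagonist gene IL1RN (0.56) rose adjusted over the list of IL-1 family ligands alone, with 0 over all genes. That list's median was -0.01 and its mean 0.36, so that the median and the test (higher, adjusted p = 0.0328, and adjusted p = 0.186 with an estimated correlation) differed in sign.

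Inflammatory lists also rose with IL-1F8. Antimicrobial genes had a median of 0.27 (adjusted p = 0.000495, and adjusted p = 0.137 with an estimated correlation), with PI3 (1.37, SE 0.237), LCN2 (1.15) and SLPI (0.96) adjusted over the list alone and 0 over all genes. The acute phase list had a median of 0.34 (adjusted p = 6.74e-05, and adjusted p = 0.154 with an estimated correlation), with 1 member, SAA2 (2.46, SE 0.694), adjusted over the list alone. SAA2 split within the group, at 8.76, 5.24 and 8.56 on replicates 1, 2 and 3. NF-kB targets and interferon-stimulated genes had medians of 0.20 and 0.18 (adjusted p = 6.74e-05 and 0.000126, and adjusted p = 0.161 and 0.154 with an estimated correlation). Barrier lists fell: terminal differentiation with a median of -0.18 (adjusted p = 6.92e-05, and adjusted p = 0.137 with an estimated correlation) and the lipid barrier with -0.22 (adjusted p = 2.48e-05, and adjusted p = 0.212 with an estimated correlation). KRT77 (-1.18, SE 0.193) was the differentiation gene that fell adjusted over the list alone. Cell cycle genes were above untreated in 27 of 28 members (median 0.28, adjusted p = 4.46e-06, and adjusted p = 0.288 with an estimated correlation). The lists of suprabasal and basal keratins and adhesion, of activation-associated keratins and partners, and of metallothioneins and NRF2 targets rose with medians of 0.13, 0.17 and 0.20 (adjusted p = 0.00621, 0.00943 and 0.000886, and adjusted p = 0.288, 0.288 and 0.161 with an estimated correlation). In the first of these the suprabasal keratins KRT1 and KRT10 stood at -0.12 and -0.18 and the adhesion genes LAMB3, ITGA6 and ITGA3 at 0.91, 0.64 and 0.62, and in the second KRT16, its 1 measured keratin, stood at 0.14. No member of either passed adjusted over the list alone. The list of immediate-early and heat shock genes and that of kallikreins and inhibitors had medians of 0.02 and 0.01 (adjusted p = 0.00228 and 0.0443, and adjusted p = 0.137 and 0.446 with an estimated correlation), both of which turned to negative values, -0.01 and -0.03, when arrays were centred on their medians, the second also with quantile normalization (-0.01). Quantile normalization gave the immediate-early list 0.04 and the list of suprabasal and basal keratins and adhesion 0.08, and either scaling gave IL-1 family ligands -0.04.

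For IL-1F8 limma called 0 genes, with 853 at an unadjusted p under 0.05 (chance 844). The smallest adjusted p, 0.0824, was shared by KRT77, TMEM164 (-1.47) and SLC8A1 (-1.21). It called 9 genes without IL-1F6 replicate 3, 2 without untreated replicate 2 or IL-1F8 replicate 2, 64 with only the IL-1F8 and untreated arrays in the fit and 2 with the replicate block. Array weights gave 505, but they set IL-1F8 replicate 3 at 58.63 and every other array at 0.21 to 1.63, so that this count rests almost wholly on 1 IL-1F8 array. None of the 100 simulated unchanged sets gave as many as 15 lists for IL-1F8, the most being 11, while fry called 0 lists by direction and 6 in its mixed form. List calls ended for IL-1 family ligands without either untreated array or IL-1F8 replicate 1 or 3, for antimicrobial genes without untreated replicate 1, for interferon-stimulated genes and EGF ligands without IL-1F8 replicate 3, and for the cell cycle without IL-1F8 replicate 2. They also ended for the list of suprabasal and basal keratins and adhesion without untreated replicate 1 or IL-1F8 replicate 2, for activation-associated keratins and partners without untreated replicate 2 or IL-1F8 replicate 3, and for kallikreins and inhibitors in 5 of 16 fits (without untreated replicate 1, IL-1a replicate 2, IL-1F5 replicate 3, IL-1F6 replicate 1 or IL-1F8 replicate 1). Of the leukocyte markers, CD68 (0.93) was higher and ITGAM (-0.60) lower adjusted over that list alone, with a list median of -0.07 (adjusted p = 0.552). Melanocyte markers were below untreated in 7 of 8 members, with a median of -0.27 (adjusted p = 0.0538, and adjusted p = 0.446 with an estimated correlation), so that the list did not pass.

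The comparison of IL-1F9 with untreated epidermis rested on 2 arrays against 2. The lipid barrier list was below untreated in 21 of 22 members (median -0.23, adjusted p = 7.72e-07, and adjusted p = 0.36 with an estimated correlation) and terminal differentiation in 16 of 18 (median -0.14, adjusted p = 9.79e-05, and adjusted p = 0.183 with an estimated correlation). Interferon-stimulated genes were above it in 25 of 29 members (median 0.24, adjusted p = 4.13e-05, and adjusted p = 0.183 with an estimated correlation). The matrix metalloproteinase and plasminogen list was above it in 14 of 16 (median 0.34, adjusted p = 0.000141, and adjusted p = 0.183 with an estimated correlation). Its members MMP9, PLAU and MMP10 stood at 1.55, 1.43 and 1.34, none passing adjusted over the list alone. Metallothioneins with NRF2 targets and antimicrobial genes rose with medians of 0.32 and 0.23 (adjusted p = 0.0145 and 0.0422, each at adjusted p = 0.41 with an estimated correlation). Adjusted over its list alone, PI3 (0.93) rose among antimicrobial genes and HBEGF (0.71) among EGF ligands, and 0 of either passed over all genes. PI3 stood at 0.61 without untreated replicate 1. SAA2 stood at 0.73 (95% confidence interval -0.87 to 2.33) and CFB at 0.00.

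For IL-1F9 limma called 0 genes, with 488 at an unadjusted p under 0.05 (chance 844) and a smallest adjusted p of 1, and fry called 0 lists in either form. Without untreated replicate 2, 1 gene passed. The median of terminal differentiation was -0.08 after quantile normalization, and that of antimicrobial genes was 0.15 with the arrays centred. The 6 lists came to 2 without IL-1F9 replicate 1 and to 3 without untreated replicate 1. In single fits the calls of the differentiation, interferon, matrix metalloproteinase and metallothionein lists ended without 1, 1, 2 and 3 of the 16 arrays, each an IL-1F9 array or untreated replicate 1, and the antimicrobial call held in 10 of 16 fits, ending without untreated replicate 1, IL-1a replicate 2, any IL-1F5 array or IL-1F9 replicate 1. For IL-1F9, 28 of 100 simulated unchanged sets gave 6 or more lists.

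**Figure D2:**
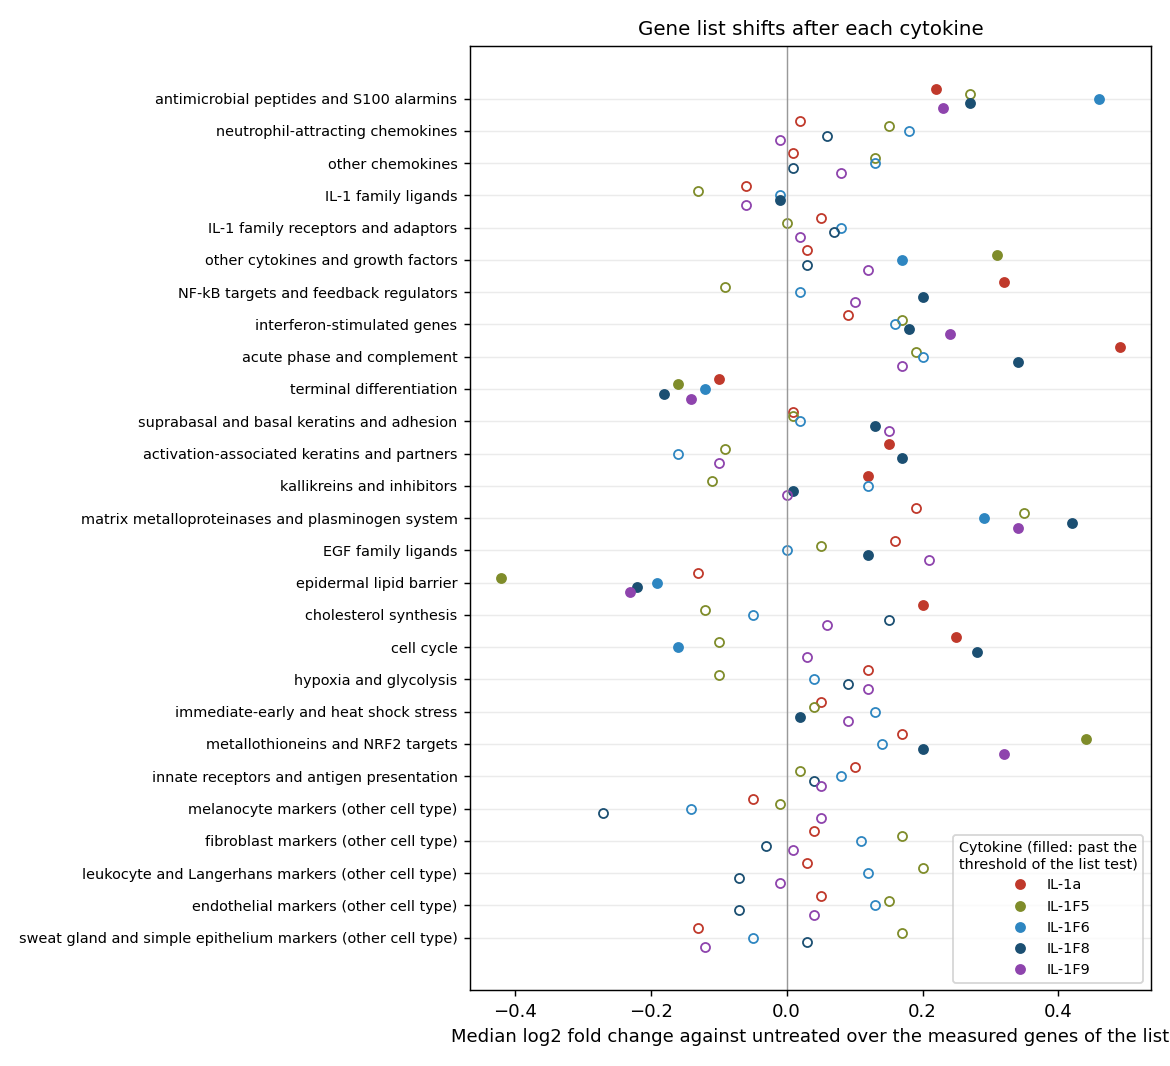
Median log2 difference from untreated (x axis) of the measured genes in each of 27 lists (y axis) for each of the 5 cytokines, shown by the points; filled points passed the list test with the preset correlation and open points did not. Terminal differentiation lies below 0 with a filled point for each cytokine, between -0.18 and -0.10, and acute phase genes reach 0.49 with IL-1a. All 5 cytokines are set against the same untreated arrays, so points of a list that lie alike are not independent of each other. Terminal differentiation did not pass in any comparison between cytokines. How often unchanged groups would shift a list alike with several cytokines was not simulated.

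The mean of the 3 IL-36 receptor agonists (IL-1F6, IL-1F8 and IL-1F9) was set against IL-1a, to ask how the responses differ, with the reservation that the doses were 5 µg/ml and 10 ng/ml. CFB was 8.54-fold lower with the agonists (log2 difference -3.09, SE 0.203, adjusted p = 3.77e-07), and KRT77 was 2.5-fold higher (1.32, SE 0.144, adjusted p = 0.000427). Each of the 8 agonist arrays lay on the same side of all 3 IL-1a arrays for both genes. SAA2 stood at -3.21 (SE 0.517) and narrowly missed the threshold (adjusted p = 0.0528), and HLA-DMA at 0.73 (adjusted p = 0.0604). As a list, acute phase and complement genes were lower with the agonists (median -0.11, adjusted p = 8.06e-10, and adjusted p = 0.058 with an estimated correlation). Adjusted over the list alone, 6 members were lower, among them CFB, SAA2, SAA1 (-1.04) and C1S (2-fold lower, and -0.63 on the log2 scale without IL-1a replicate 1), against 1 over all genes. NF-kB targets were lower (median -0.26, adjusted p = 8.06e-10, and adjusted p = 0.058 with an estimated correlation), with NFKBIZ (-0.65) and SOD2 (-0.83) adjusted over the list alone and 0 over all genes. The list of activation-associated keratins and partners was lower (median -0.22, adjusted p = 3.23e-09, and adjusted p = 0.058 with an estimated correlation). SERPINB4 (2-fold lower) and TMPRSS11D (-1.11), neither of them a keratin, passed there adjusted over the list alone and 0 over all genes. AQP5, from the sweat gland markers, was lower too (-1.44, adjusted over that list alone).

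Cell cycle, cholesterol synthesis and lipid barrier genes were also lower with the agonists than with IL-1a (medians -0.21, -0.16 and -0.12, adjusted p = 4.8e-08, 1.67e-05 and 6.7e-05, and adjusted p = 0.399, 0.218 and 0.399 with an estimated correlation). The matrix metalloproteinase and plasminogen list and interferon-stimulated genes were higher (medians 0.22 and 0.11, adjusted p = 0.0019 and 0.0117, and adjusted p = 0.257 and 0.399 with an estimated correlation). Of the former list 1 member passed adjusted over the list alone, the inhibitor TIMP2 (0.51). The interferon call ended without IL-1a replicate 2, IL-1F8 replicate 3 or IL-1F9 replicate 1, the matrix metalloproteinase call without IL-1a replicate 2 and the cell cycle call without IL-1a replicate 1. Limma called these 2 genes of 16877, with 541 at an unadjusted p under 0.05, and both passed in 16 of 16 fits that left out an array. The count was 5 without IL-1F5 replicate 3 and 4 without IL-1a replicate 2, IL-1F5 replicate 1 or IL-1F8 replicate 3. It was also 4 with dim genes left out or every probe set tested, 6 without the 2 outlying IL-1F5 arrays or the IL-1F5 group, and 8 with array weights, in which IL-1F8 replicate 3 dominates its group. Fry called 0 lists by direction and 6 in its mixed form, and the median of interferon-stimulated genes was 0.07 with the arrays centred. Of 100 simulated unchanged sets, 10 gave the observed 8 lists or more.

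Set against IL-1F5, the mean of the 3 agonists was higher in cholesterol synthesis (median 0.21, 14 of 15 members), lipid barrier (0.17, 20 of 22 members) and hypoxia and glycolysis genes (0.19, 16 of 18 members), and lower in other cytokines and growth factors (-0.12, 11 of 15 members). The adjusted p was 0.0375 for cholesterol synthesis and 0.0485 for the other 3, and each list had adjusted p = 0.683 with an estimated correlation and 0 members passing adjusted over the list alone. Outside these lists SERPINA3, an acute phase protease inhibitor, was 0.53 higher adjusted over its list alone, and the fibroblast marker THY1 (-0.52) and the sweat gland marker SCGB2A2 (-0.58) were lower adjusted over theirs. THY1 stood at -0.28 without IL-1F5 replicate 2, and without both outlying IL-1F5 arrays THY1 and SCGB2A2 stood at -0.10 and -0.28. Limma called 0 genes, with 2518 at an unadjusted p under 0.05 (chance 844), and 2564 without IL-1F5 replicate 3. Array weights gave 1640, with the same dominance of IL-1F8 replicate 3. After quantile normalization the medians of cholesterol synthesis and the lipid barrier were 0.11 and 0.10. The list count was 0 without IL-1F5 replicate 1 or 2 and 1 without either untreated array, any IL-1a array, IL-1F6 replicate 3 or IL-1F9 replicate 1, and fry called 0 lists in either form. The count was 1 with the arrays' spread as a covariate, where the direction of the list test turned for hypoxia (mean of its members 0.04, against 0.21), and 1 without both outlying IL-1F5 arrays. In the latter fit, with 1 IL-1F5 array, it turned for other cytokines, cholesterol synthesis and hypoxia (means of 0.04, 0.02 and -0.09, against -0.12, 0.19 and 0.21). The calls of other cytokines, lipid barrier, hypoxia and cholesterol synthesis held in 5, 5, 7 and 14 of 16 fits, the last ending without IL-1F5 replicate 1 or 2. Of the simulated unchanged sets, 52 of 100 gave 4 or more lists here.

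Between the agonists, cell cycle genes were lower with IL-1F6 than with IL-1F8 in 27 of 28 members (median -0.43, adjusted p = 8e-13, and adjusted p = 0.548 with an estimated correlation). The list of activation-associated keratins and partners, with 1 measured keratin, was lower with IL-1F6 in 12 of 12 members (median -0.27, adjusted p = 0.000373, and adjusted p = 0.548 with an estimated correlation). NF-kB targets, cholesterol synthesis, EGF ligands and the matrix metalloproteinase and plasminogen list were lower by medians of -0.08, -0.15, -0.20 and -0.15 (adjusted p = 0.0358, 0.0358, 0.0381 and 0.0499, and adjusted p = 0.582, 0.582, 0.548 and 0.582 with an estimated correlation). These sizes depended on the scaling: after quantile normalization NF-kB targets stood at -0.01, cholesterol synthesis at -0.06 and EGF ligands at -0.11, and with the arrays centred the first 2 stood at -0.16 and -0.23. KRT77 was higher with IL-1F6 than with IL-1F8 (log2 difference 0.72, SE 0.173) and lower with IL-1F8 than with IL-1F9 (log2 difference -0.99, SE 0.193), by limma adjusted over the list of differentiation genes alone (adjusted p = 0.0119 and 0.00151) but not over all genes. Cell cycle genes were also lower with IL-1F6 than with IL-1F9 (median -0.19, adjusted p = 0.0166, and adjusted p = 0.876 with an estimated correlation). IL-1F8 was higher than IL-1F9 in cell cycle genes (26 of 28 members, median 0.25, adjusted p = 5.14e-11, and adjusted p = 0.275 with an estimated correlation), NF-kB targets (median 0.18) and the list of activation-associated keratins and partners (12 of 12 members, median 0.18). The last 2 lists had adjusted p = 4.37e-06 and 7.23e-06, and adjusted p = 0.203 with an estimated correlation. IL-1 family ligands, acute phase genes and the list of kallikreins and inhibitors were higher with IL-1F8 as well (medians 0.17, 0.11 and 0.11, adjusted p = 0.000641, 0.000641 and 0.00948, and adjusted p = 0.203, 0.275 and 0.342 with an estimated correlation), the median of the last being 0.06 after quantile normalization.

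Limma called 0 genes between IL-1F6 and IL-1F8, IL-1F6 and IL-1F9, and IL-1F8 and IL-1F9, with 1129, 339 and 174 at an unadjusted p under 0.05, and fry called 0 lists in either form. Without IL-1F8 replicate 2, 1 gene passed in the first pair and 1 in the third. Array weights gave 5109 genes in the first pair, a count that rests almost wholly on IL-1F8 replicate 3 within its group. The first pair's 6 lists came to 3 without IL-1F6 replicate 3 or IL-1F8 replicate 3 to 10 without IL-1F8 replicate 2 and to 2 with the arrays' spread as a covariate, with the matrix metalloproteinase call holding in 5 of 16 fits and the EGF ligand call in 10. The NF-kB call ended without IL-1F6 replicate 2 or IL-1F8 replicate 1 or 3, and the cholesterol call without IL-1F6 replicate 3 or IL-1F8 replicate 1. Between IL-1F6 and IL-1F9, the 1 list, cell cycle, lost its call without IL-1F6 replicate 3 or IL-1F9 replicate 2, with a count of 0 without the former and the direction turned without the latter (mean 0.00). The count was also 0 with the replicate block or the spread covariate, and it was 2 without IL-1F6 replicate 1, IL-1F8 replicate 1 or 3 or IL-1F9 replicate 1. Between IL-1F8 and IL-1F9, the 6 lists came to 14 without IL-1F8 replicate 2 and to 2 without IL-1F9 replicate 2, which ended 4 of the 6 calls and turned the direction for kallikreins and inhibitors (mean -0.04), the cell cycle call ending without IL-1F9 replicate 1 and the acute phase and kallikrein calls also without IL-1F8 replicate 1. As many lists as observed appeared in 23, 92 and 28 of 100 simulated unchanged sets for the 3 pairs. For SAA2 the difference between IL-1F6 and IL-1F8 was -1.82, with a 95% confidence interval of -3.13 to -0.51 and an adjusted p of 0.637 by limma, so it did not pass over all genes. Its size depends on single arrays, since the IL-1F8 arrays ran from 5.24 to 8.76 in SAA2.

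Across cytokines, the genes called for IL-1a tended to stand on the same side of untreated elsewhere: 20 of 20 with IL-1F5, IL-1F6 and IL-1F8 and 19 of 20 with IL-1F9. The median ratio of their log2 differences to those with IL-1a was 0.55, 0.55, 0.72 and 0.44. Because all cytokines share the same 2 untreated arrays, unchanged groups would do likewise: in 100 simulated sets the 20 genes with the smallest p for IL-1a shared their sign in a mean of 19.2, 19.1, 18.5 and 17.5 cases, with mean ratios of 0.63, 0.64, 0.60 and 0.54. SLC8A1, TMEM164 and ULK4 were called, lower, with both IL-1a and IL-1F5, where independent draws would share 0.00415 genes and simulated unchanged sets shared a mean of 4.05. That mean came from 1 of the 100 sets, which shared 405 genes, while the others shared 0. With an array left out, SLC8A1, TMEM164 and ULK4 stayed called in 15, 13 and 3 of 16 fits for IL-1a, and in 9, 6 and 7 for IL-1F5. The correlation across genes of the log2 differences was largest between IL-1a and IL-1F8 (0.81), IL-1F5 and IL-1F6 (0.80) and IL-1F8 and IL-1F9 (0.75), and lowest between IL-1a and IL-1F5 (0.39). The simulated mean for unchanged groups in those pairs was 0.57, 0.56, 0.52 and 0.56, with 95% ranges that held each observed value. Genes are not independent replicates, so no p-value is given. Over the 6 pairs without IL-1F5 the median was 0.66, and 0.21 when each cytokine of a pair was set against a different untreated array.

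Of the 27 lists, 9 passed in none of the 10 comparisons: neutrophil-attracting chemokines, other chemokines, IL-1 family receptors and adaptors, innate receptors with antigen presentation, and the markers of melanocytes, fibroblasts, leukocytes, endothelium and sweat gland. Their medians against untreated lay between -0.27 and 0.20, and the smallest adjusted p was 0.0532. Within them CXCL8, a neutrophil chemokine, was 0.80 higher with IL-1F8 adjusted over its list alone. The IL-1F8 arrays ran from 5.68 to 6.84 in CXCL8, against 5.5 and 5.63 on the untreated arrays, so the rise was not shared by all of them. The IL-36 receptor gene IL1RL2 was lower with IL-1F5 adjusted over its list alone (-0.69, and -0.44 without untreated replicate 1). HLA-DMA was lower with IL-1a (-1.13), IL-1F5 (-0.61) and IL-1F8 (-0.57), and TLR2, a receptor for bacterial lipoproteins, was lower with IL-1F5 (-1.05), in each case adjusted over the list alone.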

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

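The 3 tests on the IL-1F8 arrays and the test of the shared untreated arrays were chosen only after the result was seen, and the tests with the arrays' spread as a covariate were added after the data were seen, though before their own values were computed. KRT77 (log2 difference 1.32) and CFB (-3.09) stood out because the effects of the agonists IL-1F6, IL-1F8 and IL-1F9 and of IL-1a differed by limma's test of the difference itself. Their values ranged from 1.18 to 1.40 and from -3.29 to -2.94 with each array left out, and both passed in 16 of 16 such fits. The random splits of the 11 arrays used another fit, which takes the 8 agonist arrays as one group in place of the mean of 3 groups. In that fit the real split called 1 gene, not the 2 reported, and 4 of 100 splits gave as many, the real one included, with a highest other of 2. The share lies under 0.05, but it concerns a count of 1 gene that another split exceeded, so it does not exclude chance. The 2 genes of the reported fit were not tested in this way. For lists, 19 of 100 splits gave the real 8 or more, with a highest other of 14, so chance is not excluded there.

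The other comparisons with at least 3 arrays a side were split in the same way. For the agonists against IL-1F5 the real split called 0 genes by limma (2518 at an unadjusted p under 0.05 over all groups), so that 100 of 100 splits had to give as many and the count of genes tests nothing. The highest other split gave 2492, a count that points to a structure of the samples, which was not examined further. For lists, the fit with the agonists as one group gave 5 in place of the 4 reported, and 50 of 100 splits gave 5 or more (highest other 14), so chance is not excluded. For IL-1F6 against IL-1F8 the 10 splits are too few for a share under 0.05: 5 of 10 gave at least the real 6 lists (highest other 12). For genes the real count was 0 by limma (1129 at an unadjusted p under 0.05), which all 10 had to reach (highest other 1).

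Within the IL-1F8 group, SAA2, CFB, LCN2 and CCL20 were high on replicates 1 and 3 and not on replicate 2. An exchange of labels with another group would need a partner with a high SAA2 value, and the highest outside the IL-1a and IL-1F8 groups was 6.57, against 8.56 for the lower of the pair, while CFB at 6.60 or less stayed under the lowest IL-1a array (8.54). A narrow spread of replicate 2 is argued against by its standard deviation of 2.20, at the top of the 2.12 to 2.20 of the 5 arrays with high SAA2. RNA of IL-1a-treated tissue mixed into replicates 1 and 3 is argued against because SAA2 would need a share of at least 35.1% and CFB at most 14.4%. A difference between cultures in how they answered IL-1F8 may remain as a hypothesis, which was not tested and which the labels do not address.

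The 20 genes called for IL-1a stood on the same side of untreated with nearly every other cytokine. With the spread of the arrays as a covariate the median ratio to IL-1a was 0.63, against 0.55 without. This does not decide whether the spread was the cause. Unchanged groups sharing the 2 untreated arrays gave simulated mean ratios of 0.63, 0.64, 0.60 and 0.54, so the ratio could stay near its value in either case. Noise of the 2 shared untreated arrays stays open: the median covariance of the log2 differences over the 10 pairs was 0.0368. For unchanged groups the simulated 95% bounds of single pairs had medians over the pairs of -0.00506 and 0.0903, and the simulated means a median of 0.0282. The observed value lay inside these bounds, but the range of the median over 10 pairs was not simulated. A response shared between the cytokines, which the design names, also stays open, since with 2 untreated arrays it was not separated from that noise.

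With IL-1F5, 3003 genes had an unadjusted p under 0.05, and the 5 called genes were lower. With the spread of the arrays as a covariate the count was 1997, where chance gives 844 on average. How far this count ranges for unchanged arrays with correlated genes was not computed. The covariate therefore does not decide whether the spread was the whole cause of the count. For the 5 genes the median log2 difference was -1.13 with the covariate and -1.26 without (median SE 0.211 and 0.199). The calls of the 5 genes ended all the same with the covariate, where the smallest adjusted p by limma was 0.0725. Why they ended was not tested. Whether IL-1F5 itself, or the arrays of replicates 1 and 2 that stand apart, gave the count was not settled either, since both belong to the same 3 arrays.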

How the results depend on the processing

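The covariate for the arrays' spread and the fits without the 2 outlying IL-1F5 arrays or without the IL-1F5 group were chosen only after the data were seen, and the others before the data were examined. The gene counts were 20 (IL-1a), 5 (IL-1F5), 2 (agonists against IL-1a) and 0 in the other 7 comparisons by limma, and the list counts 8, 4, 6, 15 and 6 for IL-1a, IL-1F5, IL-1F6, IL-1F8 and IL-1F9, 8 and 4 for the agonists against IL-1a and IL-1F5, and 6, 1 and 6 for IL-1F6 against IL-1F8, IL-1F6 against IL-1F9 and IL-1F8 against IL-1F9. Of the alternative values for single named genes, 3160 kept their direction and side of the threshold, 202 lost the call, 109 gained one and 0 turned. Many of these could not turn, since leaving out an array of a group not compared leaves a gene's difference unchanged. For lists 1114 kept both, 280 lost the call and 6 turned. CFB and KRT77 held in each alternative for IL-1a and for the agonists against IL-1a. The RNA quality covariate was not run, as control probe sets were not used here. Array signal over background was not measured, and leaving out the 6531 genes under the median probe set mean of 5.94 limits the dim genes.

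For single genes, array weights gave 44 for IL-1a, 1807 for IL-1F5, 505 for IL-1F8, 8 and 1640 for the agonists against IL-1a and IL-1F5, and 5109 for IL-1F6 against IL-1F8. They set IL-1F8 replicate 3 at 58.63 and every other array at 0.21 to 1.63, so that the IL-1F8 values in these counts rest almost wholly on that array. Leaving out dim genes gave 15 for IL-1F5 and 4 for the agonists against IL-1a, where fewer genes are adjusted for. The mean of a gene's probe sets gave 1 for IL-1F5, and testing every probe set gave 0 there and 4 for the agonists against IL-1a. Centring arrays on the median gave 110 for IL-1F5. Using only the groups compared gave 0 for IL-1F5 and 64 for IL-1F8, and the replicate block gave 421 and 2. The residuals gave no sign that the replicate numbers pair the arrays: 36 same-numbered pairs had correlations of -0.68 to 0.52 with a median of 0.04, against -0.03 for the others. Pairing is not excluded, since residuals from group means of 2 or 3 arrays show little of it and the labels do not address it. The spread covariate gave 32 for IL-1a and 0 for IL-1F5. Without the 2 outlying arrays, which leaves 1 IL-1F5 array assumed to vary like the other groups, IL-1F5 gave 0, and the agonists against IL-1a gave 6, as they did without the IL-1F5 group. Apart from the filter on dim genes, the cause was not tested.

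For lists, the estimated correlation gave 1 for IL-1a and 0 in the other 9 comparisons. Fry by direction gave 1 for IL-1a, 1 for IL-1F5 and 0 elsewhere. Its mixed form gave 7 for IL-1a, 4 for IL-1F5, 6 for IL-1F8 and 6 for the agonists against IL-1a. It gave 0 for IL-1F6, IL-1F9, the agonists against IL-1F5 and the 3 pairs of agonists. The spread covariate gave 7 for IL-1F5, 3 for IL-1F6, 1 for the agonists against IL-1F5, 2 for IL-1F6 against IL-1F8 and 0 for IL-1F6 against IL-1F9, where the replicate block also gave 0. Without the 2 outlying arrays, again with 1 IL-1F5 array, there were 7 for IL-1F5 and 1 for the agonists against IL-1F5. In that last comparison the direction of the list test turned without the 2 arrays for other cytokines (mean of its members 0.04), cholesterol synthesis (0.02) and hypoxia (-0.09), and with the covariate for hypoxia (0.04). The cause was not tested.

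With each array left out in turn, where a group left with 1 array is assumed to vary like the others, the lowest and highest gene counts were 2 (without untreated replicate 1) and 25 (without IL-1F5 replicate 3) for IL-1a, 0 and 2097 for IL-1F5 (the highest without its replicate 3), 0 and 13 for IL-1F6 and 0 and 9 for IL-1F8 (both highest without IL-1F6 replicate 3), and 0 and 1 for IL-1F9 (without untreated replicate 2). For the agonists they were 2 and 5 against IL-1a and 0 and 2564 against IL-1F5 (both highest without IL-1F5 replicate 3), and 0 and 1 for IL-1F6 and for IL-1F9 against IL-1F8 (without IL-1F8 replicate 2). List counts were 1 to 9 for IL-1F6 (without untreated replicates 1 and 2), 2 to 8 for IL-1F9 (lowest without its replicate 1, highest without untreated replicate 2), 0 to 5 for the agonists against IL-1F5 (without IL-1F5 replicate 1 and IL-1F6 replicate 1), 3 to 10 for IL-1F6 against IL-1F8 (without IL-1F6 replicate 3 and IL-1F8 replicate 2), 0 to 2 for IL-1F6 against IL-1F9 (without IL-1F6 replicates 3 and 1) and 2 to 14 for IL-1F8 against IL-1F9 (without IL-1F9 replicate 2 and IL-1F8 replicate 2). The mean of cell cycle genes ranged from -0.38 to 0.00 for IL-1F6 against IL-1F9, and that of kallikreins and inhibitors from -0.04 to 0.28 for IL-1F8 against IL-1F9, and the direction of the test turned in each without IL-1F9 replicate 2 (0.00 and -0.04). The median correlation of log2 differences over the 6 pairs without IL-1F5, 0.66, was 0.55 to 0.77 in these fits. It was 0.21 with the untreated arrays split between the cytokines and 0.91 over the 4 genes past the F test. With the IL-1F5 arrays as the control of one cytokine it was -0.15. That control is not shared, but it also subtracts any response that IL-1F5 has in common with the other cytokines. The value therefore does not decide whether the shared untreated arrays gave the 0.66. The cause was not tested.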

Other observations

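The correlation of the first principal component with the spread of the arrays, and the genes singled out on the IL-1F8 and IL-1F6 arrays, were chosen only after the result was seen. Among growth factor and cytokine transcripts of keratinocytes, BTC lay below untreated with each of the 5 cytokines, and HBEGF and IL1B lay above it. BTC, betacellulin of the EGF family, stood at -1.19, -1.13, -0.81, -1.07 and -0.69 with IL-1a, IL-1F5, IL-1F6, IL-1F8 and IL-1F9, while HBEGF, another EGF receptor ligand, stood at 0.81, 0.56, 0.58, 1.00 and 0.71. Adjusted over the list of EGF ligands alone, BTC passed with IL-1a, IL-1F5, IL-1F6 and IL-1F8, and HBEGF with IL-1a, IL-1F6, IL-1F8 and IL-1F9, and neither passed over all genes. With IL-1a, EPGN (0.75) and NRG1 (0.85) passed as well, but they stood at 0.34 and 0.56 without untreated replicate 2, and EPGN at 1.17 without replicate 1. BTC with IL-1F5 stood at -0.53 without the 2 outlying IL-1F5 arrays. IL1B stood at 1.32, 1.52, 1.32, 2.00 and 1.08 in the same order, and passed over its list alone with IL-1F8. The 2 IL-1F9 arrays differed in IL1B, at 6.60 and 7.41, against 5.92 on both untreated arrays. IL36G, which encodes IL-1F9 itself, was 1.01 higher with IL-1a adjusted over its list alone (adjusted p over all genes 0.285), and stood at -0.10, -0.01, 0.54 and -0.03 with the others. The IL-1F8 arrays ran from 9.92 to 10.91 in IL36G, against 10.00 on both untreated arrays. KLK12, a kallikrein, rose with IL-1a (0.87) and IL-1F8 (0.83), and PLA2G3, a secreted phospholipase of the lipid barrier list, rose with IL-1a (0.86), each adjusted over its list alone. The shared untreated arrays enter all of these values.

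Genes separated the IL-1F8 arrays in more than one way. IL1B (7.74, 8.16 and 7.88), PLAU (9.52, 10.02 and 10.14), MMP9 (10.11, 10.98 and 11.11) and MMP10 (8.38, 9.52 and 8.81) lay above both untreated arrays on replicates 1, 2 and 3, where the untreated arrays reached at most 5.92, 8.31, 9.45 and 7.12. CCL20, a chemokine, was 8.80, 7.06 and 8.44 on the same arrays, and LCN2 was 10.59, 9.13 and 10.64. In the IL-1F6 group, replicate 3 lay near untreated in IL1B (6.04), PLAU (8.22) and UPK1A (11.01), while replicates 1 and 2 had 7.62 and 8.06, 9.51 and 10.09, and 9.13 and 10.16. Across all 16 arrays the first principal component, with 41.3% of the variance, went with the arrays' standard deviation (Pearson r -0.92 and Spearman rho -0.92, each with a permutation p of 1e-05, the smallest that 100000 permutations can give, and r -0.89 without the 2 arrays farthest from the median standard deviation).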
